A study of Daphnia pulex and Daphnia magna with 6 samples.

How the data were processed

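Whole-body DNA of 6 pools of animals was sequenced after bisulfite conversion, 3 pools of D. pulex clone TCO* and 3 of D. magna clone Xinb3. Per the labels' protocols, each biological replicate pooled 30 daphnids of about 14 days, grown at 20 °C; the D. pulex and D. magna cultures used different media. DNA was sheared to about 300 bp and converted with a commercial kit, per the labels' protocols. The submitters' processing notes name CASAVA 1.5, Trim Galore 0.3.2, Bowtie2 2.1.0 and Bismark 0.9.0, without their roles or settings. The genome build and whether duplicate reads were removed are not given in the sources used here.

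The deposited values are counts: for each listed cytosine, the number of methylated and of unmethylated calls, in separate files for CpG, CHG and CHH and for reads of the top and bottom strand, 6 files a library and 36 in all. The lowest total was 5 calls in every D. pulex file and 1 call in every D. magna file, so cytosines with fewer than 5 calls were left out of the D. pulex files before deposit. D. pulex positions were given as intervals counted from 0 and D. magna positions counted from 1; both are given here counted from 1. A CpG cytosine on the top strand was paired with the cytosine 1 bp further on the bottom strand.

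The methylation level was the methylated calls divided by all calls, over every listed cytosine of a context. Limiting D. magna to cytosines with at least 5 calls gave CpG levels of 0.868%, 0.830% and 0.800% in replicates 1, 2 and 3, against 0.877%, 0.840% and 0.808% over all cytosines. Because a level is taken within a library, no scaling between libraries was needed. The non-CpG level of CHG and CHH together was each library's background. CpG cytosines with at least 5 calls were tested against it with a binomial test for a higher level, and were called methylated at a Benjamini-Hochberg adjusted p under 0.05 within the library. Levels at called sites used sites with at least 10 calls. Windows of 1 kb needed at least 5 tested sites, and the top 5% of windows were ranked by level. The windows named were fixed by rule before the data were examined: the 10 per species with the highest level in their lowest library among windows with at least 20 sites of 5 or more calls in every library, the longest run of adjacent windows at 50% or more, and the highest and lowest scaffolds with at least 1000 tested sites.

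The calling step was tested on simulated calls placed at the coverage of the real CpG sites of replicate 1 of each species. Sites simulated at 90% were called in 99.9% of cases in both species, sites at 50% in 91.4% (D. pulex) and 89.7% (D. magna), and sites at 20% in 56.7% and 46.1%. Partly methylated sites were therefore missed more often than fully methylated ones at these depths. Sites at background were called in 0.00348% and 0.00312% of cases. Background was simulated at 0.5% in both species. The real non-CpG level varied with coverage, in D. pulex replicate 1 from 0.838% at 5 to 7 calls to 0.388% at 40 to 99. The simulation therefore does not give the rate of false calls at the real background. With a background matched to coverage, the called share in D. pulex was 0.965%, against 1.01% as called.

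The species were compared by the exact two-sided permutation test of the 6 library values, over 20 assignments with a smallest possible p of 0.1. CpG and non-CpG levels were compared within libraries by the exact two-sided sign-flip permutation test, over 64 sign patterns. In all 11 measures were compared between the species; the raw p-values are given, and the lowest is 0.138 after Benjamini-Hochberg adjustment over the 11. Each replicate number occurs in both species, but the animals, genomes and media differ and no site is shared, so the numbers were not used to pair libraries. The labels give each library as a biological replicate from its own pool, so the libraries of a species were counted as 3 replicates.

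Alternatives fixed before the data were examined were other coverage minimums, an unweighted mean over sites, leaving out sites above 3 times the median coverage, each strand alone, a stricter adjusted p of 0.01, the CHH level as background, thinning every site to 10 calls, summing the strands, a definition by a level of 50% or more, windows of 500 bp and 5 kb, neighbours within 100 bp, leaving out each replicate, and a replicate block. A background matched to the coverage of each site, D. pulex replicate 3 alone and, for the level at called sites, thinning to 10 calls and sites at 0.5 to 1.5 times the median coverage were added after the data were seen. Planned analyses of exons and introns, exon rank, gene family size and gene lists needed an annotation of the assembly behind the deposited positions and were not run. The gene table available was of assembly ASM2113471v1, whose sequences are not the deposited scaffolds. The work used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pyarrow 21.0.0 and matplotlib 3.10.9.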

Results

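Cytosine methylation was measured across the genome by bisulfite sequencing in 2 species of water flea, the small freshwater crustaceans Daphnia pulex and Daphnia magna. Bisulfite converts unmethylated cytosines, which are then read as thymine, so each read over a cytosine gives a methylated or an unmethylated call. The 6 libraries comprised 3 biological replicates of the D. pulex clone TCO* and 3 of the D. magna clone Xinb3, each made from 30 pooled whole animals at 14 days without treatment. Over CpG cytosines the D. pulex libraries held 149821667 to 158128280 calls and the D. magna libraries 125645003 to 167489295 calls. The median listed CpG cytosine had 14 or 15 calls in D. pulex and 10 or 11 calls in D. magna. The comparison throughout is between the species, which also differed in clone and culture medium. With 3 libraries against 3, the smallest p an exact two-sided permutation test can give is 0.1, so no difference between the species could reach 0.05. Binomial intervals cover counting error only, since reads without molecular identifiers are not independent molecules. The study's title links gene body methylation to gene family size; genes, exons and families were not analysed here, because the annotation given was of another assembly than the positions in the files.

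The first question was how much cytosine methylation each genome carried and in which sequence context. Methylation was sparse in both species. The CpG methylation level was 0.918% ± 0.0583 (SD, n = 3) in D. pulex and 0.842% ± 0.0342 (SD, n = 3) in D. magna. CHG cytosines, in which H is any base but G, stood at 0.445% ± 0.0884 (SD, n = 3) in D. pulex and 0.326% ± 0.00992 (SD, n = 3) in D. magna. CHH cytosines stood at 0.525% ± 0.124 (SD, n = 3) and 0.362% ± 0.0105 (SD, n = 3). Non-CpG calls include unconverted and misread cytosines, so the level over CHG and CHH together served as the background of each library.

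CpG cytosines lay above that background in 6 of 6 libraries. The CpG level exceeded the non-CpG level of the same library by 0.452 percentage points on average (exact two-sided sign-flip permutation test, p = 0.031, the smallest possible with 6 libraries). The excess was 0.416 ± 0.0568 percentage points (SD, n = 3) in D. pulex and 0.489 ± 0.0256 (SD, n = 3) in D. magna. As measured the mean CpG level was thus higher in D. pulex, and after subtracting the non-CpG level it was lower. D. pulex replicate 3 alone differed from the D. magna mean excess by only -0.00860 percentage points. The ranges of the species overlapped for both measures. CpG levels ran from 0.859% to 0.976% in D. pulex and from 0.808% to 0.877% in D. magna. The excess ran from 0.372 to 0.480 percentage points in D. pulex and from 0.461 to 0.512 in D. magna. The exact permutation p was 0.2 for the level and 0.2 for the excess. On the highly covered scaffolds described under Other observations, D. pulex had a mean CpG level of 0.336% and a mean non-CpG level of 0.424%. In D. magna the levels there were 0.357% and 0.351%. The non-CpG level may thus overstate the CpG background in D. pulex. Whether it does so on the other scaffolds was not tested. The lower excess therefore does not show less CpG methylation in D. pulex. The difference in the excess, D. pulex minus D. magna, was -0.0730 percentage points and its size depended on the cytosines counted: -0.0206 with at least 10 calls per cytosine, -0.151 as an unweighted mean over cytosines, and -0.118 without those above 3 times the median coverage (exact permutation p = 0.6, 0.1 and 0.1). For CHG and CHH the ranges of the species did not overlap (exact permutation p = 0.1 for each, the smallest possible). The non-CpG level was 0.523% and 0.604% in D. pulex replicates 1 and 2 but 0.379% in replicate 3, against 0.347% to 0.365% in D. magna. Set against D. magna, D. pulex replicate 3 alone was higher by 0.0176 percentage points for CpG, 0.0238 for CHG and 0.0282 for CHH, while the differences of the means were 0.0760, 0.119 and 0.163. As unweighted means over cytosines the CHG and CHH differences were 0.205 and 0.262.

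**Figure D1:**
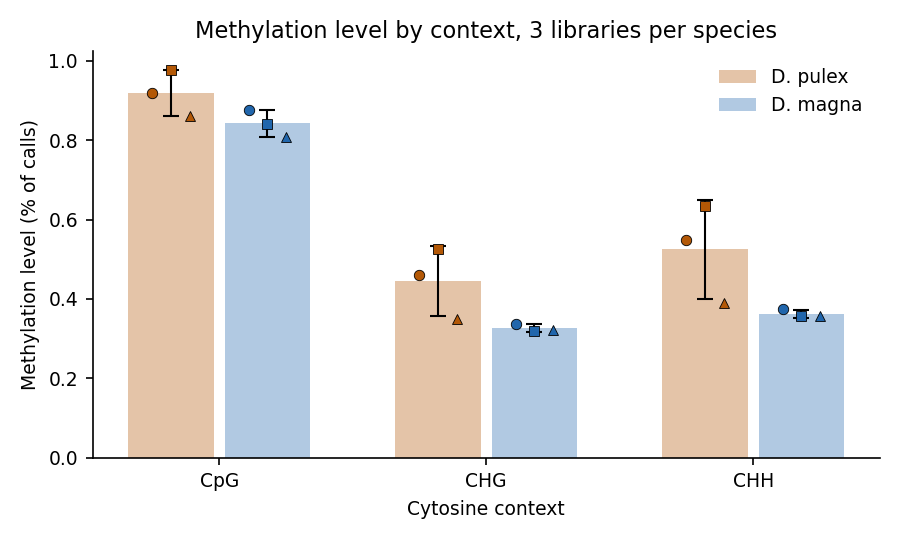
Bars show the mean methylation level, in percent of calls, for CpG, CHG and CHH cytosines of each species; error bars are the SD of 3 libraries and circles, squares and triangles are replicates 1, 2 and 3. CpG stands highest in both species, at 0.918% in D. pulex and 0.842% in D. magna, and the D. pulex libraries spread more widely in CHG and CHH.

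The second question was how many CpG sites were methylated, and whether they were the same between replicates. About 1 CpG site in 100 was called methylated in both species. Of 6615903 to 7024132 CpG cytosines with at least 5 calls in D. pulex, 1.01% ± 0.0311 (SD, n = 3) were called methylated against the library's own background. In D. magna 0.934% ± 0.00471 (SD, n = 3) of 6760539 to 6965334 were called. The ranges of the species did not overlap (exact two-sided permutation p = 0.1), but the size of the difference depended on the definition. It was 0.0712 percentage points as called, 0.139 with at least 10 calls per site, 0.0169 at an adjusted p under 0.01, and 0.000356 when a methylated site was defined as one at 50% or more with at least 10 calls, where the species means were 0.7061% and 0.7058%.

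The same sites were called in library after library. Of 66619 D. pulex sites called in any library and tested in all 3, 49960 were called in all 3, or 75.0% (95% Wilson interval 74.7% to 75.3%). In D. magna 50580 of 55938 were, or 90.4% (95% Wilson interval 90.2% to 90.7%). Independent calls would have given 5.69 and 4.32 such sites. The intervals treat sites as independent, although strand partners and neighbouring sites were often called together, so they may be too narrow. Unadjusted tests of levels at called sites gave low p-values between replicates more often in D. pulex than in D. magna, but almost none remained after adjustment. Among sites called in any library with at least 10 calls in all 3, a chi-square test of the calls of the 3 replicates gave an unadjusted p under 0.05 at 11.2% of 37567 D. pulex sites and 5.34% of 26400 D. magna sites, where about 5% would be so without any difference if calls were independent. After Benjamini-Hochberg adjustment, 1 D. pulex site and 0 D. magna sites differed. The 5% holds only for sites not picked by their calls, and here a site called in only 1 library also entered. Depth was not matched between the species either. The contrast of 11.2% and 5.34% therefore does not show that D. pulex replicates differed more.

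Methylated sites were more completely methylated in D. magna than in D. pulex. The median level at called sites with at least 10 calls was 80.3% ± 0.444 (SD, n = 3) in D. pulex and 90.9% in each D. magna library. Sites at 80% or more made up 51.2% ± 0.673 (SD, n = 3) of called sites in D. pulex and 68.6% ± 0.221 (SD, n = 3) in D. magna. Sites between 20% and 80% made up 42.5% ± 0.499 (SD, n = 3) and 27.1% ± 0.404 (SD, n = 3). The ranges of the species did not overlap for the median level or for the share at 80% or more (exact two-sided permutation p = 0.1 for each, the smallest possible). Over the alternative settings, of which thinning and sites of ordinary coverage were chosen after the data were seen, the difference in the share at 80% or more, D. pulex minus D. magna, lay between -20.2 and -15.4 percentage points.

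**Figure D2:**
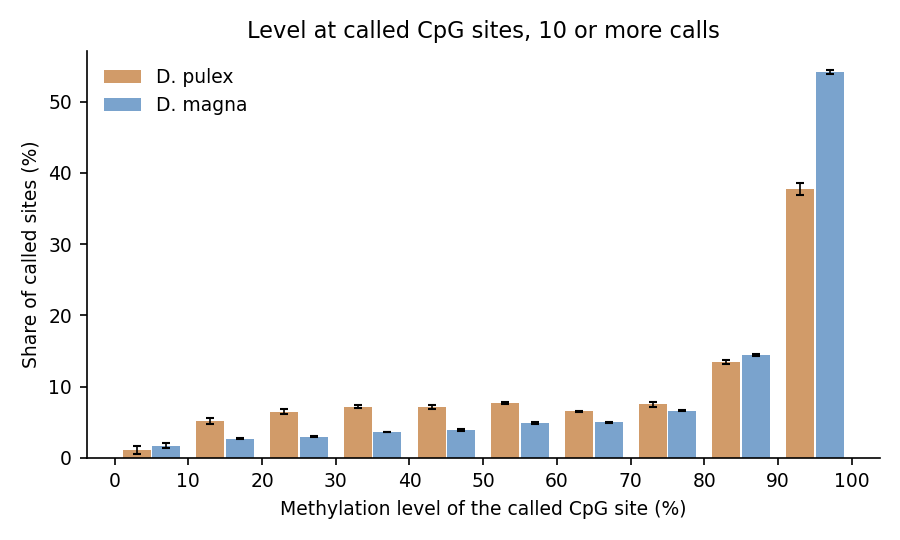
The x axis gives the methylation level of called CpG sites with at least 10 calls in steps of 10 percentage points and the y axis the share of called sites in percent; bars are means and error bars the SD of 3 libraries. The highest step holds 37.7% of called sites in D. pulex and 54.1% in D. magna, and D. pulex has the larger share in the steps from 10% to 80%.

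A CpG is the same on both strands, so its cytosines can be compared across the strands. Where a called cytosine had a tested partner, the partner was also called in 87.7% ± 0.834 (SD, n = 3) of cases in D. pulex and 95.7% ± 0.0972 (SD, n = 3) in D. magna (exact two-sided permutation p = 0.1, the smallest possible). The difference, D. pulex minus D. magna, was -8.06 percentage points, and -3.43 after every site was thinned to 10 calls. No pair was at 80% or more on a strand and at 20% or less on the other in all 3 libraries, among 3667 D. pulex pairs and 1895 D. magna pairs with at least 10 calls on both strands and a strand at 80% or more, which allows shares of up to 0.0818% and 0.158%.

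The third question was how methylated sites were arranged. They lay in short clusters. The next tested CpG on the same strand was also called for 59.8% ± 0.715 (SD, n = 3) of called sites in D. pulex and 71.0% ± 0.119 (SD, n = 3) in D. magna, where random placement would give 1.00% and 0.930%. The D. pulex minus D. magna difference was -11.2 percentage points (exact two-sided permutation p = 0.1, the smallest possible), and -6.21 with at least 10 calls per site. Within 11 to 25 bp of a called site, 62.5% ± 4.58 (SD, n = 3) of sites were called in D. pulex and 89.4% ± 0.923 (SD, n = 3) in D. magna. At 301 to 500 bp the shares were 7.29% ± 0.111 and 7.72% ± 0.050 (SD, n = 3). They were lowest at 751 to 1000 bp, at 1.40% ± 0.0805 and 1.28% ± 0.0207, and stood at 2.33% ± 0.0319 and 2.29% ± 0.0366 at 1001 to 1500 bp.

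**Figure D3:**
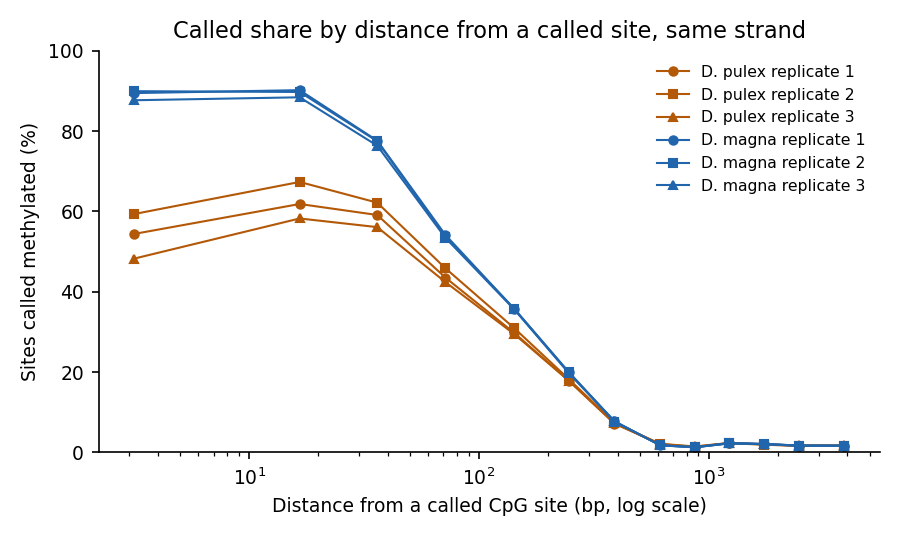
The x axis is the distance in bp from a called CpG site on the same strand, on a log scale with each point at the geometric middle of its distance class, and the y axis the share of tested sites called methylated, in percent; each line is a library. The D. magna lines start near 89% and the D. pulex lines between 48.3% and 59.4%, and all 6 lines lie close together beyond 300 bp.

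Methylation was concentrated in a small part of each genome. Among 1 kb windows with at least 5 tested CpG sites, 4.49% ± 0.0517 (SD, n = 3) in D. pulex and 4.55% ± 0.0762 (SD, n = 3) in D. magna had a CpG level of 10% or more. This difference was within the spread between libraries (exact two-sided permutation p = 0.4), and its direction turned, to 0.0593 percentage points higher in D. pulex, with at least 10 calls per site. Otherwise D. pulex stayed lower, by a size that varied: the difference was -0.0650 as measured, -0.163 with 500 bp windows and -0.358 with 5 kb windows (exact permutation p = 0.1 for each), -0.0369 without D. pulex replicate 3, -0.0253 without D. magna replicate 1 and -0.101 without D. magna replicate 3. The 5% of windows with the highest level held 69.0% ± 1.15 (SD, n = 3) of called sites in D. pulex and 74.4% ± 0.589 (SD, n = 3) in D. magna (exact two-sided permutation p = 0.1, the smallest possible). They held 2.93% and 2.96% of tested sites. Since these windows were ranked by the methylation that defines the calls, a large share is built in; with the calls of CpG pairs placed at random over the tested pairs, a comparison chosen after the data were seen, the share was 21.7% ± 0.367 and 21.5% ± 0.310 (SD, n = 3), and at most 22.4% and 22.0% in any of 20 placements per library. The difference, -5.40 percentage points, was -2.08 at an adjusted p under 0.01, -3.34 with a background matched to coverage and -10.5 with 5 kb windows.

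Methylated windows mostly had no methylated neighbour among the windows tested. A window without the minimum number of sites tested in all 3 libraries could not count as a neighbour. Isolation may therefore be overstated and runs cut short. In D. pulex 4547 of 114626 windows tested in all 3 libraries were at 10% or more in each, and 3542 of them had no such neighbour. In D. magna 4510 of 114458 windows were, and 3671 had no such neighbour. The next window was also methylated for 11.6% of these windows in D. pulex and 9.82% in D. magna, above the highest of 100 random placements, 4.11% and 3.61%. The longest run was 4 windows in both species. At 50% or more, with at least 20 CpG sites, 50 windows in D. pulex and 65 in D. magna passed in every library, and no 2 of them were adjacent.

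The windows named here are the 10 per species with the highest level in their lowest library, among windows with at least 20 CpG sites tested in every library. Positions are those of the files, counted from 1, and the genome build is not given in the sources used here. In D. pulex the leading window, scaffold_191 from 39001 to 40000, had a CpG level of 85.2% ± 1.27 (SD, n = 3) over 25 sites with a mean of 14.4 calls. The windows to its left and right were under 1% in every library. It was followed by scaffold_2 from 1469001 to 1470000 at 85.0% ± 2.24 (SD, n = 3) over 22 sites with 20.2 calls, and scaffold_9 from 1135001 to 1136000 at 70.1% ± 0.107 (SD, n = 3) over 32 sites with 17.4 calls. The other 7 lay on scaffold_3, scaffold_41, scaffold_2, scaffold_142, scaffold_49, scaffold_77 and scaffold_1, with mean levels between 65.4% and 73.8%. In D. magna the leading window, scaffold02190 from 1551001 to 1552000, was at 95.2% ± 1.66 (SD, n = 3) over 21 sites with 11.8 calls. The window to its left was at 7.83%, 10.1% and 8.18% in replicates 1, 2 and 3, and the window to its right did not have 5 sites tested in all 3 libraries. It was followed by scaffold00868 from 773001 to 774000 at 88.5% ± 1.40 (SD, n = 3) over 34 sites with 17.3 calls, and scaffold01361 from 2301001 to 2302000 at 83.5% ± 1.82 (SD, n = 3) over 24 sites with 20.1 calls. The other 7 lay on scaffold02861, scaffold01009, scaffold01867, scaffold00512, scaffold03373, scaffold01409 and contig24810, with mean levels between 70.3% and 79.6%.

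**Figure D4:**
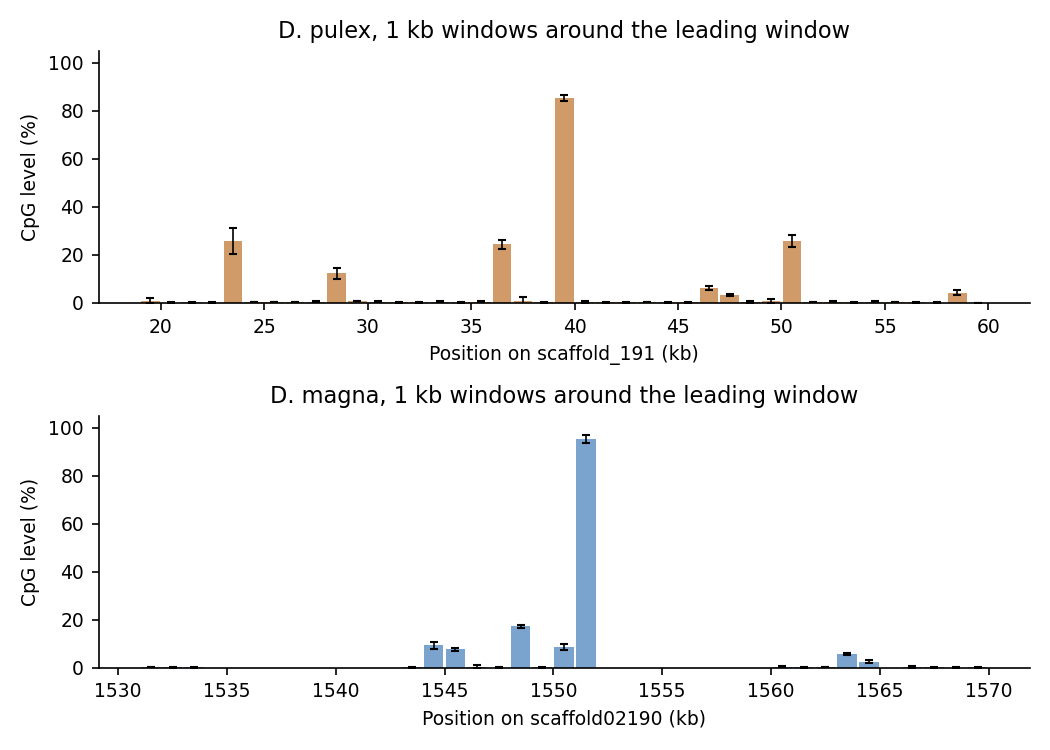
The x axes give the position in kb on scaffold_191 of D. pulex and scaffold02190 of D. magna and the y axes the CpG level, in percent, of 1 kb windows; bars are means and error bars the SD of 3 libraries, and a window with fewer than 5 sites tested in all 3 libraries has no bar. The leading windows stand at 85.2% and 95.2%, with most of the surrounding windows close to 0.

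Levels also differed between scaffolds, over a far smaller range. Among 282 D. pulex scaffolds with at least 1000 tested CpG sites the median level was 0.758%. The highest was scaffold_199 at 3.53% ± 0.198 (SD, n = 3) over 2237 sites with a mean of 26.3 calls, and the lowest scaffold_648 at 0.295% ± 0.0389 (SD, n = 3) over 1929 sites with 34.7 calls. Among 341 D. magna scaffolds the median was 0.619%. The highest was scaffold00106 at 3.91% ± 0.175 (SD, n = 3) over 3098 sites with 18.8 calls, and the lowest scaffold02966 at 0.257% ± 0.0492 (SD, n = 3) over 1054 sites with 17.5 calls. In both species the lowest scaffolds were at or below the non-CpG level of the libraries.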

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

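The tests of strand partners, neighbouring cytosines, ordinary coverage and thinning below were chosen after the patterns had been seen but before their own values were, and the tests of sites with 1 methylated allele and of sequence differences from the reference after both.

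Signal appeared outside the CpG measurement, in single non-CpG cytosines. The species comparisons count these only within the CHG and CHH levels and the background of each library. In D. pulex 308 CHG and 1030 CHH cytosines were at 50% or more in all 3 libraries, among those tested with at least 10 calls. In D. magna 4 CHG and 17 CHH cytosines were, out of similar numbers tested. The median level of the D. pulex cytosines was 88.5% ± 0.332 (SD, n = 3). CHG methylation on both strands is argued against by the partners 2 bp away on the other strand, of which 0% were called among 151 to 184 tested per D. pulex library, which allows up to 1.99%. Unconverted stretches of DNA are argued against by the level of other non-CpG cytosines within 50 bp, at most 0.789% in any D. pulex library. Windows with a CpG level of 10% or more were taken from D. pulex replicate 1 alone. The cytosines lay in them 15.4 times as often as such windows occur, 69.3% against 4.50%. A candidate explanation, still a hypothesis, is that the sequenced D. pulex animals differ from the reference at these positions, so that the cytosine is in fact part of a methylated CpG. Sequence of the animals was not analysed here, and a biological non-CpG methylation of single cytosines within methylated windows remains open too.

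Called CpG sites were less completely methylated in D. pulex than in D. magna, and technical explanations were set against the difference between the species. Reads from extra or collapsed copies are argued against, since at sites with at least 10 calls and 0.5 to 1.5 times the median coverage the share at 80% or more still differed by 20.2 percentage points. The minimum of 10 calls, not 0.5 times the median, set the lower bound in both species. The medians were taken over cytosines with at least 5 calls in D. pulex and at least 1 call in D. magna, so the ranges were not matched. Depth is argued against, since the difference was 15.4 percentage points with every site thinned to 10 calls. Thinning cannot test the higher minimum coverage of the D. pulex files, since the levels used only sites with at least 10 calls in both species. Sites with 1 of 2 alleles methylated would fall between 35% and 65% in 81.2% of cases at the D. pulex depth, but only 48.9% of the excess of D. pulex sites under 80% lay there, so such sites may account for part of the difference and not for all of it. Partial methylation across the cells of the pooled animals, a difference between the species, clone and medium remain open and were not tested.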

How the results depend on the processing

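D. pulex replicate 3 alone, the coverage-matched background and, for the level at called sites, thinning and ordinary coverage were chosen after the data were seen; the other settings were fixed before. Of 154 alternative values of the 11 species differences, 13 could not move (the block, and 2 calling rules for the window share); of the other 141, 140 kept their direction. The exception was the share of 1 kb windows at 10% or more, which became higher in D. pulex by 0.0593 percentage points with at least 10 calls per site; the cause was not tested. Since no exact test of 3 against 3 can pass 0.05, these settings speak for direction and size only. Where the ranges of the species did not overlap, leaving out 1 library or taking D. pulex replicate 3 alone could not reverse the direction. The 140 include such values, so their number does not measure how stable the direction is. The size moved by over 1.5 times in 30 of the alternatives. Without D. pulex replicate 2 the difference was 0.0469 percentage points for CpG, 0.0789 for CHG and 0.108 for CHH. D. pulex replicate 3 alone differed from the D. magna mean by 0.0176, 0.0238 and 0.0282 percentage points for CpG, CHG and CHH, by -0.00860 for CpG minus non-CpG, by -18.1 for sites at 80% or more and by -0.121 for windows. The called share differed by 0.0329 percentage points with strands summed and 0.0317 with the coverage-matched background. Strand symmetry differed by -3.90 percentage points with at least 10 calls and -4.37 at an adjusted p under 0.01. CpG minus non-CpG, 0.452 percentage points over 6 libraries, lay between 0.440 and 0.468 with 1 library left out, where 5 libraries allow no p under 0.0625. Its size moved more with the cytosines counted. It was 0.417 with at least 10 calls, 0.634 without sites above 3 times the median coverage and 0.644 as an unweighted mean over sites.

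Agreement between replicates rose in D. pulex from 75.0% to 81.4% with at least 10 calls, 81.7% at an adjusted p under 0.01 and 82.3% after thinning, and was 74.3% without sites of very high coverage; between any 2 libraries it was 80.2% to 81.5%. In D. magna, from 90.4%, the values were 91.1%, 91.5%, 90.9% and 91.4%, and 93.3% to 93.4% between any 2 libraries. The rise between 2 libraries follows from asking for fewer of them; the cause of the others was not tested. With a replicate block, the CpG level differed by 0.0760 percentage points (exact sign-flip permutation p = 0.25, the smallest possible with 3 pairs); with or without it no p can pass 0.05, so this does not bear on stability. Exon, intron, exon rank, gene family and gene list results were not run.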

Other observations

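The tests of CpG density below were fixed before their results were seen, while the comparisons of neighbouring sites and of non-CpG levels by coverage were chosen after the data were seen.

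Methylated DNA held fewer CpG sites in both species. The share of CpG was taken among cytosines with at least 5 calls. In windows with a CpG level of 10% or more, CpG made up 11.98% ± 0.198 (SD, n = 3) of these cytosines in D. pulex and 12.1% ± 0.107 (SD, n = 3) in D. magna. In windows under 2% it made up 23.9% ± 0.305 and 23.1% ± 0.0944 (SD, n = 3). The lower share was present at every coverage, the smallest difference over 6 libraries and 3 coverage classes being -10.1 percentage points. Selection of CpG-poor windows by the level threshold is argued against, since within 250 bp of called sites the share was lower than around uncalled sites by at least 14.1 percentage points in each library (smallest difference -14.1). That CpG sites have been lost where they are methylated, since methylated cytosine mutates readily to thymine, is a hypothesis that starts from this lower share, so -10.1 cannot tell it from a difference in base composition between coding and other sequence, and both may hold.

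Neighbouring CpG sites differed more sharply in D. pulex. Within 1 to 25 bp of a site at 80% or more, with at least 10 calls at both, 10.5% ± 0.0566 (SD, n = 3) of CpG sites on the same strand were under 10% in D. pulex and 0.207% ± 0.0415 (SD, n = 3) in D. magna. At 26 to 50 bp the shares were 10.998% ± 0.282 and 6.62% ± 0.310 (SD, n = 3).

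The non-CpG level in D. pulex replicates 1 and 2 fell from 0.838% and 1.00% at cytosines with 5 to 7 calls to 0.388% and 0.420% at 40 to 99 calls, and was higher again from 100 calls to under 1000, 0.412% and 0.482%, and at 1000 or more, 0.422% and 0.472%. In replicate 3 the levels of these 4 classes were 0.466%, 0.331%, 0.354% and 0.377%. In D. magna the level went from between 0.376% and 0.387% at 5 to 7 calls to between 0.329% and 0.356% at 40 to 99 and between 0.347% and 0.365% at 1000 or more. The non-CpG level was also higher in windows with a CpG level of 10% or more than in windows under 2%, 0.846% ± 0.190 against 0.465% ± 0.0982 (SD, n = 3) in D. pulex and 0.389% ± 0.00800 against 0.343% ± 0.0110 (SD, n = 3) in D. magna. On scaffolds covered at 20 times the median or more, the CpG level was 0.336% ± 0.0344 (SD, n = 3) in D. pulex and 0.357% ± 0.0161 (SD, n = 3) in D. magna, against 0.969% ± 0.0638 and 0.889% ± 0.0376 (SD, n = 3) on the rest. The highly covered scaffolds numbered 24 to 26 per library in D. pulex and 359 to 429 in D. magna. The non-CpG level on them was 0.424% ± 0.0435 and 0.351% ± 0.0102 (SD, n = 3). The CpG level there was thus below the non-CpG level in D. pulex, and within the spread between libraries of it in D. magna.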
